A study of Mus musculus with 8 samples.

How the data were processed

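Total RNA from C3H10T1/2 cells was labelled with biotin and hybridised to Affymetrix mouse 430A arrays, 1 array per sample, per the labels' protocols. The titles placed 4 samples in the vehicle group and 4 in the BMP7 group, with replicate numbers 1 to 4 in each. The dose of 3.3 nM and the 3 days of treatment come from the design text and the treatment protocol. The value table deposited by the authors holds 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The version, the scaling target and any probe masking are not given in the sources used here. On every array the 2% trimmed mean of the signals was between 1500.4 and 1500.7, so the values had been scaled to a common level. Detection calls were not among the columns, so the fallback filter named for that case was used. A second table deposited by the authors holds, per the file headers, the mean intensity of each group, their ratio and a p-value for each probe set. To 6 decimals, the authors' means equalled the means of the 4 columns of each group, their ratio the quotient of these means, and their p-value an unequal-variance test on the linear signals. That table also has 8 columns of per-sample values whose names match no label, and these were not used. The choice of value table was therefore settled by which columns could be tied to samples.

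Signals were taken as log2 without a pseudocount. After 64 Affymetrix control probe sets were left out, 22626 remained, and those with a mean log2 signal over the 8 arrays above the 40th percentile (8.335, a linear signal of 322.9) were tested, 13575 in all. The filter does not use the groups. Gene symbols came from the platform annotation and were updated through the Entrez ID for 20828 probe sets. Of the 22626 probe sets left, 21453 had 1 symbol, 482 had several and 691 had none. No gene was named from a probe set with several, and 535 tested probe sets had no single gene. Each gene was represented by its tested probe set with the highest mean signal, which gave 8375 genes. No genome was used here, so no coordinates are given.

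The comparison was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, 6 residual and 5.09 prior degrees of freedom), with the data.table package (1.17.8). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 37 lists with at least 5 tested members, and again with the correlation estimated for each list. The fry test asks whether a list's genes move, on balance, one way or, in its mixed form, in either direction, and compares them with no other genes. Measures of the arrays were compared with an exact permutation test over all 70 assignments. Standard errors of list medians come from a jackknife over arrays. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

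The 39 lists cover BMP targets, BMP and activin receptors, TGF-beta, YAP/TEAD, Notch, Wnt, Hedgehog, FGF and IGF signalling, lineage genes (cartilage, osteoblast, tendon, skeletal and smooth muscle, adipocyte, brown fat, mesenchymal progenitor), markers of other cell types (macrophage and leukocyte, endothelial, epithelial, neuronal and glial), metabolism, stress, cell cycle, interferon, inflammation, matrix, homeobox and reference genes. Named are the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap (leaving out identifiers that are not gene names), up to 4 members past the threshold with the largest change of each list described, and a set of genes followed whatever their result. Of that set, Prdm16 had no probe set with this single gene. A gene that the rule picked is not reported here. The groups, the test, the filter, the lists, the naming rule and most alternatives were chosen before the data were examined.

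The fit was tested on simulated data made from the 13575 probe sets with the real group sizes. Of 100 probe sets changed by 1 on the log2 scale 32% were recovered, and of 100 changed by 2, 86%; 0 had the wrong direction and 4 of 122 calls were unchanged probe sets. Small changes are therefore often missed with 4 arrays per group. The noise was drawn independently for each probe set and array, with the same spread in both groups. The real arrays correlated less within vehicle than within BMP7. This simulation therefore cannot show how often the fit makes false calls on the real arrays. In a simulation of the 37 lists over 8375 genes, the 1 shifted list was called and 0 of the others were. Its genes were drawn independently of each other, whereas the correlation estimated between cell cycle genes was 0.388. It therefore cannot show how often the list test at the preset correlation makes false calls on the real arrays.

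The alternatives were quantile normalization, a common median, log2 of the signal plus 16, no filter, a filter at the 60th percentile, no intensity trend, array weights, a per-probe-set test without moderation, the replicate number as a block, leaving out each array in turn, the mean of a gene's probe sets, camera with an estimated correlation, and fry. Added after the data were seen were the log2 spike-in level (geometric mean of 9 control probe sets) as a covariate, the log2 beta-actin 3'/5' ratio as a covariate, the mean log2 3'/5' ratio of beta-actin, Gapdh and pyruvate carboxylase as a covariate, and an unequal-variance test on linear signals. Any 2 arrays shared at most 18 identical signals, so no array was a copy of another.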

Results

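C3H10T1/2 cells are a multipotent, fibroblast-like line from mouse embryonic mesenchyme. Confluent cultures received either vehicle or 3.3 nM BMP7, a secreted bone morphogenetic protein of the TGF-beta family, and total RNA was profiled 3 days later on Affymetrix mouse 430A arrays. Each group held 4 arrays, and the single comparison asked which transcripts differed between BMP7-treated and vehicle-treated cells. Of 22690 probe sets, 13575 lay above the signal filter and were tested, and 8375 genes were each represented by 1 of them. The small number of arrays limits the precision of every value. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

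Vehicle replicate 3 stood apart from the other arrays. The median MAS5 signal was 488 on that array and between 532 and 622 on the other 7, and its mean correlation with the others was 0.832, against 0.885 to 0.919 for the rest. Its 3'/5' signal ratio was 6.55 for beta-actin and 3.36 for Gapdh, where the other arrays reached at most 1.40 and 1.35. Raised ratios were not limited to that array. The Gapdh ratio was 0.895 and 1.35 on vehicle replicates 1 and 2 and lay between 0.725 and 0.797 on the BMP7 arrays. The pyruvate carboxylase ratio was 5.49 on each of these vehicle arrays, 4.58 on vehicle replicate 3 and 1.54 on vehicle replicate 4, against 1.42 to 2.81 on the BMP7 arrays. Exact two-sided permutation tests of the log2 ratios between the groups gave p = 0.0857 for Gapdh, 0.114 for pyruvate carboxylase and 0.171 for beta-actin. The bacterial spike-in transcripts had a geometric mean signal of 6284, 7483, 11273 and 4588 on vehicle replicates 1 to 4 and lay between 4112 and 4781 on the BMP7 arrays, a difference with an exact two-sided permutation p of 0.0857 (smallest possible 0.0286). Arrays correlated with each other at r = 0.851 to 0.943 (mean 0.892) within vehicle and at 0.946 to 0.965 (mean 0.956) within BMP7. Between vehicle and BMP7 arrays r was 0.806 to 0.941 (mean 0.883). These values are over the tested probe sets, which are not independent replicates. The main axis of variation (first principal component) held 46.5% of the variance. Vehicle replicates 1 to 4 had scores of -13.9, -24.2, -88.2 and 6.86 on it, against 24.4 to 32.9 on the BMP7 arrays. Within vehicle, the scores rose as the spike-in signals fell.

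**Figure D1:**
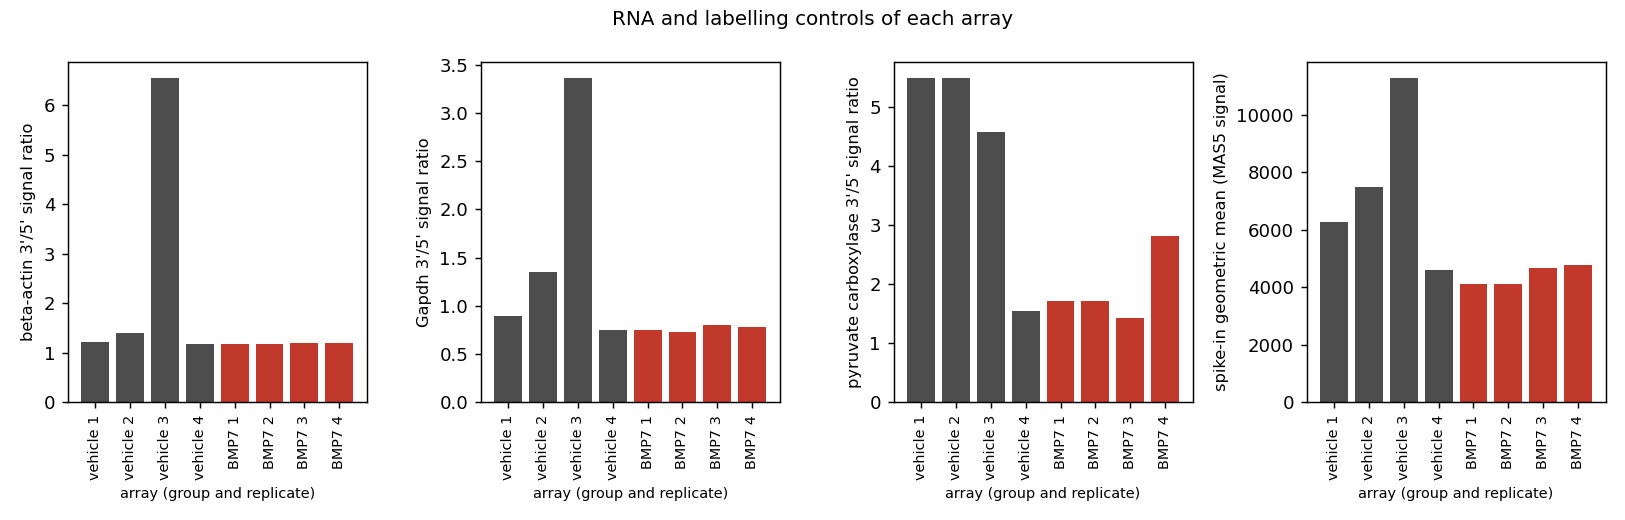
Bars give, for each array, the 3'/5' signal ratio of the beta-actin, Gapdh and pyruvate carboxylase control probe sets and the geometric mean MAS5 signal of the spike-in probe sets, with vehicle arrays in grey and BMP7 arrays in red. Vehicle replicate 3 is the highest for beta-actin, Gapdh and the spike-ins, at 6.55, 3.36 and 11273, and vehicle replicates 1 and 2 are the highest for pyruvate carboxylase, at 5.49.

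Genes of the BMP response were among the largest rises in BMP7-treated cells. Smad6, an inhibitory Smad of BMP signalling, rose 10.0-fold, from a log2 signal of 9.29 ± 0.30 in vehicle to 12.6 ± 0.23 in BMP7 (SD, n = 4 arrays each), a log2 change of 3.33 (SE 0.21, limma adjusted p = 6.55e-05). Hey1, a transcriptional repressor that is also a Notch target, rose by 3.70 (SE 0.32, adjusted p = 0.000482), and Id4, an inhibitor of basic helix-loop-helix transcription factors, rose by 2.93 (SE 0.28, adjusted p = 0.000666). Id3, Smad7 and Bambi, a decoy receptor, rose by 1.36, 1.56 and 1.78. Of the 19 tested BMP target and feedback genes, 8 rose, none fell and 11 did not pass; adjusted over the list alone, 11 rose and 1 fell. The list's median log2 change was 0.68 (quartiles 0.22 and 1.73), with a camera adjusted p of 1.65e-08 and an adjusted p = 0.0504 with an estimated correlation. Id1 and Id2 did not pass, with log2 changes of 0.95 (adjusted p = 0.0509) and 0.68 (adjusted p = 0.145; 1.79 for a second Id2 probe set, adjusted p = 0.247). Id1 lay near the threshold: it passed with quantile normalization, log2 of the signal plus 16, the stricter filter, array weights, the replicate number as a block or the mean of probe sets, and without vehicle replicate 3 or 4 (adjusted p from 0.00891 to 0.0492). The vehicle means of Hey1 and Id4 lay under the filter level of 323 (8.34 on the log2 scale), so their folds are imprecise. Hey1 stayed above the filter in only 4 of the 8 fits that left out 1 array. The number of members that rose was 5 without BMP7 replicate 2, 3 or 4. With no filter 7 of 26 members rose and 0 fell. Those that rose included Atoh8 (3.19, adjusted p = 0.00598), which the filter had left out and which was named after its values were seen. Bambi did not pass without vehicle replicate 1 or any 1 of the BMP7 replicates, where its adjusted p reached 0.139. The median was 0.40 with the spike-in level as a covariate and 0.42 with the mean log2 3'/5' ratio of beta-actin, Gapdh and pyruvate carboxylase as one.

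Across the array, 404 probe sets changed (207 higher and 197 lower in BMP7, limma adjusted p under 0.05; 2937 at an unadjusted p under 0.05), and 334 of them changed at least 2-fold (174 higher and 160 lower). By gene, 123 rose and 142 fell, while with the mean of a gene's probe sets 222 rose and 172 fell. In 261 of the 265 genes that passed by their representative probe set, the 4 BMP7 arrays all lay on one side of the 4 vehicle arrays. Such separation occurred in 15.2% of all tested genes, against 2.86% by chance. Of the 265 genes, 96 had more than 1 tested probe set, and 32 had another that passed in the same direction and 0 had one that passed in the opposite direction. With every array shifted to a common median the split was 180 higher and 286 lower, or 38.6% higher in place of 51.2%, because the median log2 change of all genes moved from 0.00 to -0.10. Such a shift moves every gene alike and so tests no list; relative to that median the list medians were, by construction, 0.86 for cell cycle genes, 0.68 for BMP targets, 0.83 for cartilage genes, 0.37 for cholesterol synthesis, -0.86 for interferon response genes, -0.68 for inflammatory genes, -0.33 for matrix genes, -0.85 for tendon genes and -0.27 for fatty acid oxidation.

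The counts depended on single arrays and on the variance model. Without vehicle replicates 1, 3 and 4 in turn, 146, 703 and 1042 probe sets changed, and without BMP7 replicates 1 to 4 in turn 207, 93, 90 and 112; the corresponding genes numbered 101, 455, 565, 145, 70, 70 and 84. Array weights gave 1760 probe sets, a per-probe-set test without moderation 83, the spike-in level as a covariate 49, the mean 3'/5' ratio as a covariate 92, and an unequal-variance test on linear signals 4. With the spike-in covariate, 4 BMP target genes rose, 3 interferon, 2 inflammatory and 2 matrix genes fell, and 1 cartilage gene rose; with the ratio covariate 5, 5, 2, 3 and 1 did. With array weights 45 cell cycle genes rose, 18 matrix genes fell and 6 rose, and 5 fatty acid oxidation genes fell and 1 rose. Without moderation 5 BMP target and 1 cartilage gene rose and 4 interferon, 1 inflammatory, 2 matrix and 1 tendon gene fell, while 0 cell cycle genes rose and 0 fatty acid oxidation genes fell. Without the intensity trend 4 cell cycle and 2 cartilage genes rose and 4 matrix genes and 1 tendon gene fell, and with no filter 5 cell cycle genes rose and 5 matrix genes and 1 tendon gene fell. Of the 68 named genes that passed, 22 still did with the spike-in covariate and 32 with the ratio covariate. Of the 404 probe sets, 100% of those tested in each of these fits kept their direction. They had been picked from the same arrays, so this was close to fixed in advance.

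**Figure D2:**
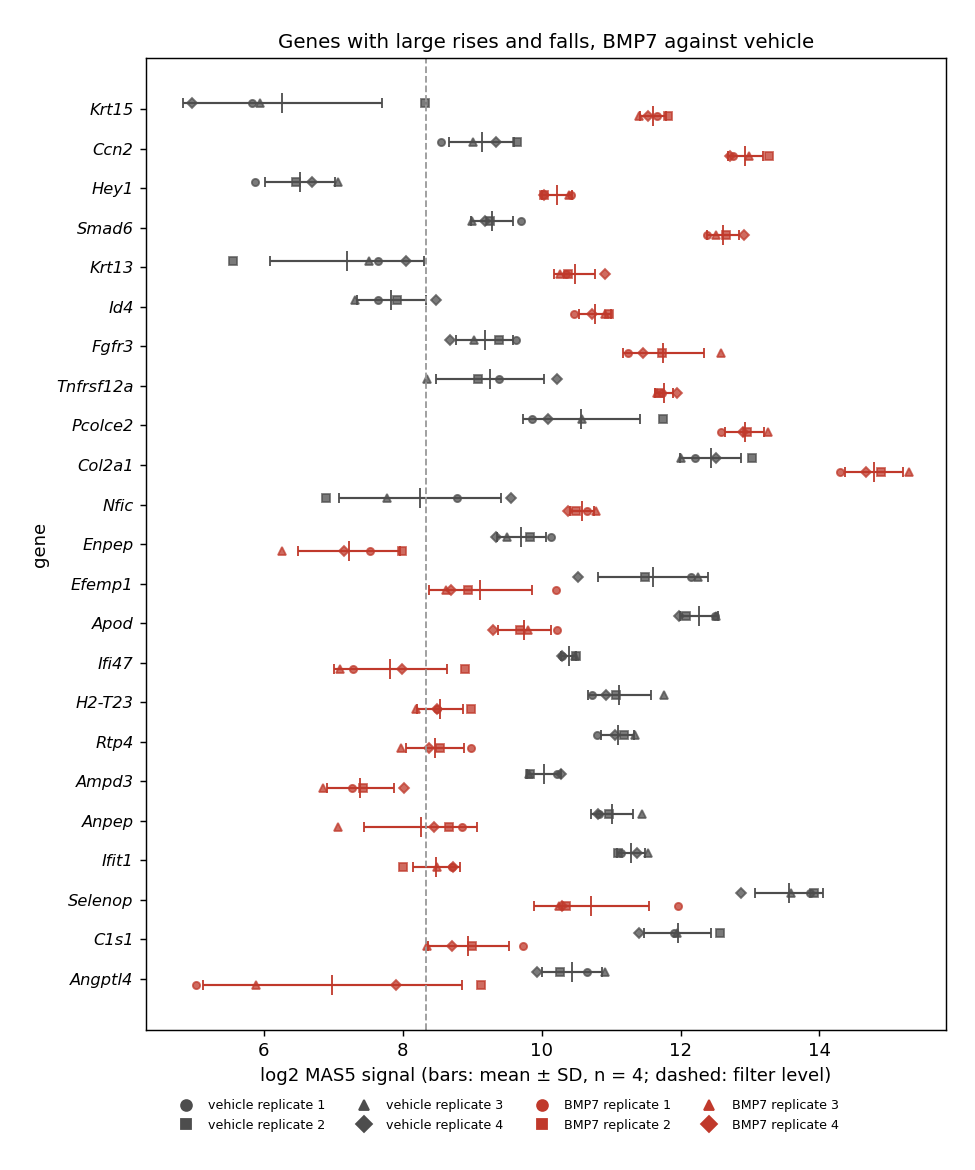
Points give the log2 MAS5 signal of each array for 11 genes with large rises and the 12 with the largest falls among those that passed, with the mean ± SD per group (n = 4; vehicle grey, BMP7 red) and the filter level of 8.34 dashed. The vehicle means of Krt15, Hey1, Krt13, Id4 and Nfic lie under the filter level, as do the BMP7 means of Enpep, Ifi47, Ampd3, Anpep and Angptl4.

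The largest rise was that of Krt15, a type I keratin, at 5.33 on the log2 scale (SE 0.57, adjusted p = 0.00158). Ccn2, a matricellular growth factor, rose by 3.80 (SE 0.25, adjusted p = 6.55e-05). Krt13, a second keratin, rose by 3.28, Fgfr3, a fibroblast growth factor receptor, by 2.57, Tnfrsf12a, the TWEAK receptor, by 2.51, Pcolce2, an enhancer of procollagen processing, by 2.35, and Nfic by 2.33. Krt15 and Krt13 had vehicle means under the filter level, so their folds start from dim signals. A second Nfic probe set had 1.07 (adjusted p = 0.318), and Nfic did not pass with the mean of its probe sets (adjusted p = 0.0668). The largest falls were those of Angptl4, an inhibitor of lipoprotein lipase (-3.45, SE 0.74, adjusted p = 0.0347), C1s1, a complement protease (-3.01, SE 0.32, adjusted p = 0.00158), and Selenop, a selenium transport protein (-2.84, SE 0.38, adjusted p = 0.00404). Anpep and Enpep, a pair of cell surface aminopeptidases, fell by 2.76 and 2.47, and Apod, an apolipoprotein, fell by 2.52. Ampd3, H2-T23, a class Ib histocompatibility gene, and Efemp1, a fibulin, fell by 2.65, 2.58 and 2.49. Of the 23 genes in the plot of signals by array, 20 passed in every leave-one-out fit that tested them. Angptl4 did not pass without vehicle replicate 1 or 2 or BMP7 replicate 1, 3 or 4 (adjusted p up to 0.122), Efemp1 without vehicle replicate 1 or BMP7 replicate 2, 3 or 4 (up to 0.0629), and Nfic without vehicle replicate 1 or any 1 BMP7 replicate (up to 0.105). With the spike-in level as a covariate, 15 of the 23 passed, with Tnfrsf12a at 1.61 and Nfic, which did not pass, at 1.34. With the mean 3'/5' ratio as a covariate 19 passed.

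Interferon response genes were lower in BMP7-treated cells. Ifit1 and Ifit3, antiviral effectors, had log2 changes of -2.80 (SE 0.23, adjusted p = 0.000329) and -2.14 (SE 0.25, adjusted p = 0.00269), and Rtp4 and Ifi47, an interferon-induced GTPase, had -2.63 (SE 0.25, adjusted p = 0.000666) and -2.57 (SE 0.36, adjusted p = 0.00499). Of 24 tested members, 6 fell, none rose and 18 did not pass, and adjusted over the list alone 15 fell. All 24 had negative log2 changes, with a median of -0.86 (quartiles -1.54 and -0.41). The camera adjusted p was 1.21e-12, and this was the only list called with an estimated correlation (adjusted p = 0.0430). Leaving out any 1 array gave list p-values up to 9.12e-09 and 5 to 8 members that fell, and the stricter filter left 9 members tested, of which 3 fell. The 4 named members passed in each leave-one-out fit; Rtp4 and Ifi47 were not tested under the stricter filter.

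Genes of inflammation and NF-kappaB signalling were also lower. Vcam1, an adhesion molecule, had a log2 change of -2.44 (SE 0.22, adjusted p = 0.000617), and the chemokines Ccl2, Ccl7 and Ccl9 had -2.13 (SE 0.38), -1.77 (SE 0.29) and -1.77 (SE 0.31), with adjusted p of 0.0177, 0.0111 and 0.0140. With the mean of its probe sets Vcam1 had -1.60 and passed. A second Ccl9 probe set had -1.29 and did not pass (limma adjusted p = 0.146). Of 19 tested members, 6 fell, none rose and 13 did not pass; adjusted over the list alone 8 fell and 1 rose. The median was -0.68 (camera adjusted p = 0.000315; adjusted p = 0.0504 with an estimated correlation), and it was -0.39 without BMP7 replicate 1 and -0.44 without vehicle replicate 1. The call ended with the stricter filter on dim probe sets (median -0.10, adjusted p = 0.325), which kept the brighter members alone. Only 2 members fell without vehicle replicate 1 or BMP7 replicate 3, and 3 without BMP7 replicate 2. Ptgs2, named after its values were seen, rose without vehicle replicate 3 (1.02, adjusted p = 0.0458) and with array weights. Ccl2 and Ccl9 did not pass without vehicle replicate 1 or BMP7 replicate 2 or 3, with adjusted p up to 0.0731 and 0.0561, and Ccl7 not without BMP7 replicate 3 (0.0505).

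Cell cycle genes were higher as a group. Tk1, which phosphorylates thymidine for DNA synthesis, rose by 1.57 on the log2 scale (SE 0.31, adjusted p = 0.0255), and Mcm5 and Mcm3, subunits of the replicative helicase, by 1.53 (SE 0.28, adjusted p = 0.0182) and 1.37 (SE 0.27, adjusted p = 0.0246). Ccnb1, a mitotic cyclin, rose by 1.24 (SE 0.29, adjusted p = 0.0495). Of 59 tested members, 11 rose, none fell and 48 did not pass, and adjusted over the list alone 42 rose; 57 had positive changes, with a median of 0.86 (quartiles 0.60 and 1.13). The camera adjusted p was 5.42e-21, with an adjusted p = 0.290 with an estimated correlation, which was 0.388 between members. Another Mcm3 probe set, a dimmer one, had 0.14 (SE 0.33) and did not pass. The spike-in signals and the Gapdh and pyruvate carboxylase 3'/5' ratios were higher on 3 of the vehicle arrays. On vehicle replicate 4 they lay within the range of the BMP7 arrays. That array had the highest vehicle signals of Tk1 (2880), Mcm5 (1845), Mcm3 (3267) and Ccnb1 (1850), the nearest to the BMP7 arrays. Its Ccnb1 signal lay above that of BMP7 replicate 1 (1779), so the groups overlapped for this gene. With the spike-in level as a covariate the median was 0.60, with the mean 3'/5' ratio as a covariate it was 0.63, and no member passed in either fit (0 of 59). No member passed (0 of 59) without vehicle replicate 1 or without BMP7 replicate 2, 3 or 4; 3 rose without BMP7 replicate 1, 5 without vehicle replicate 2 and 32 without vehicle replicate 4. The list p stayed at or under 6.51e-17 in the leave-one-out fits. The highest adjusted p in those fits was 0.0967 for Tk1, 0.0816 for Mcm5, 0.0986 for Mcm3 and 0.157 for Ccnb1, which in 7 of the 8 did not pass. With the mean of a gene's probe sets 20 members rose, and in the test without moderation 0 did.

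Extracellular matrix genes were lower more often than higher. Decorin (Dcn) and lumican (Lum), small leucine-rich proteoglycans that bind collagen, had log2 changes of -2.34 (SE 0.27, adjusted p = 0.00226) and -2.15 (SE 0.26, adjusted p = 0.00276). Col18a1 and the protease gene Adamts1 had -2.15 (SE 0.39, adjusted p = 0.0188) and -1.90 (SE 0.25, adjusted p = 0.00361). Of 61 tested members, 8 fell, 1 rose and 52 did not pass; adjusted over the list alone 19 fell and 5 rose. The 1 that rose was the fibrillin gene Fbn2 (log2 change 1.06, adjusted p = 0.0491), named after its values were seen. The median was -0.33 (camera adjusted p = 0.000792; adjusted p = 0.290 with an estimated correlation), and with quantile normalization it was -0.10 and the list was not called (adjusted p = 0.183). It was -0.18 with the spike-in covariate and -0.21 with the mean 3'/5' ratio covariate. Without vehicle replicate 1, 4 fell, without vehicle replicate 2, 5, without BMP7 replicate 1, 5, and without BMP7 replicates 2, 3 and 4 in turn 3 each. Of the leave-one-out fits, Fbn2 passed only in the one without vehicle replicate 3 (adjusted p up to 0.152 in the others); without vehicle replicate 2 Lox and without vehicle replicate 4 Timp1, named after their values were seen, rose in its place. Col18a1 did not pass without BMP7 replicate 2, 3 or 4 (adjusted p up to 0.0791).

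Cartilage genes rose in part. Col2a1, which encodes the main cartilage collagen, rose by 2.35 (SE 0.26, adjusted p = 0.00199), Papss2, which supplies sulphate for proteoglycans, by 2.22 (SE 0.51, adjusted p = 0.0441), Col9a1 by 1.96 (SE 0.41, adjusted p = 0.0330) and Sox9, the chondrogenic transcription factor, by 1.54 (SE 0.34, adjusted p = 0.0403). A second Sox9 probe set had a positive log2 change and did not pass (adjusted p = 0.0593). The other 9 of the 13 tested members did not pass, among them the aggrecan gene Acan (0.84, SE 0.56, adjusted p = 0.405). Adjusted over the list alone, 4 rose and 2 fell. The 2 were Matn2 (-1.34, adjusted p = 0.0548 over all probe sets) and Trps1 (-0.92, adjusted p = 0.0537), named after their values were seen. Both fell over all probe sets with quantile normalization, a common median, the stricter filter, array weights, the mean of a gene's probe sets or the beta-actin covariate, and without vehicle replicate 3 or 4. The list's median was 0.84, with a camera adjusted p of 0.0453 and an adjusted p = 0.590 with an estimated correlation. The call ended without vehicle replicate 1, 3 or 4 (adjusted p = 0.0712, 0.0780 and 0.401) or BMP7 replicate 3 (0.164), with no filter (0.0708), the stricter filter (0.135), array weights (0.0776), the mean of a gene's probe sets (0.0859) or the beta-actin ratio as a covariate (0.0658). The median was 0.38 without BMP7 replicate 3, 0.47 without vehicle replicate 4 and 0.48 with no filter. With no filter 3 of 29 members rose and 0 fell. Those that rose included Col10a1 (log2 change 4.605, adjusted p = 0.0022), which the filter had left out and which was named after its values were seen. Col2a1 passed in every leave-one-out fit. Sox9 did not pass without vehicle replicate 1 or any 1 BMP7 replicate (up to 0.139), Papss2 without these or vehicle replicate 3 (up to 0.145), and Col9a1 without vehicle replicate 1 or BMP7 replicate 1, 2 or 3 (up to 0.119). Just 1 cartilage gene rose without vehicle replicate 1 or BMP7 replicate 1, 2 or 3, and 2 rose without BMP7 replicate 4.

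Tendon and ligament genes were lower, with a median log2 change of -0.84 over 9 tested members. The 2 that fell were Dcn and the matrix glycoprotein gene Tnc (-1.62, SE 0.36, adjusted p = 0.0400), both also counted with the matrix genes, and 7 did not pass; adjusted over the list alone 3 fell. The camera adjusted p was 0.0286 (adjusted p = 0.328 with an estimated correlation), and the call ended without vehicle replicate 2 or 3 (0.0973 and 0.0608), BMP7 replicate 1 (0.05003), with array weights (0.0965) or with the spike-in, beta-actin or mean 3'/5' ratio covariate (0.128, 0.0658 and 0.126). The median was -0.45 without vehicle replicate 2, -0.48 with the spike-in covariate and -0.51 with the mean ratio covariate. Tnc did not pass without vehicle replicate 1 or 2 or BMP7 replicate 2, 3 or 4 (adjusted p up to 0.136), which left 1 member that fell in each of these fits.

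Cholesterol synthesis genes were higher and fatty acid oxidation genes lower as lists. None of the 23 tested cholesterol synthesis genes passed (0 rose and 0 fell by limma; 20 positive and 3 negative changes), and 0 rose or fell adjusted over the list alone. Their median was 0.37, with a camera adjusted p of 0.0124 and an adjusted p = 0.561 with an estimated correlation. The call ended with array weights (median 0.17, adjusted p = 0.0776), with the spike-in covariate (0.08, adjusted p = 0.577), with the mean 3'/5' ratio covariate (0.17, adjusted p = 0.189) and with the beta-actin covariate (adjusted p = 0.0627). Without vehicle replicate 4, 1 member, Srebf2, named after its values were seen, rose (0.89, adjusted p = 0.0475). Among 28 fatty acid oxidation genes, Pdk4, a kinase that restrains pyruvate oxidation, fell by 2.42 (SE 0.48, adjusted p = 0.0268) and 27 did not pass; adjusted over the list alone 1 rose and 2 fell. The median was -0.27, with a camera adjusted p of 0.0333 and an adjusted p = 0.561 with an estimated correlation. That call ended without vehicle replicate 1 or 3 (0.114 and 0.0714), BMP7 replicate 2 or 3 (0.0666 and 0.0832) or with the spike-in, mean 3'/5' ratio or beta-actin covariate (0.128, 0.139 and 0.0658). The median was -0.14 without vehicle replicate 3 and -0.15, -0.17 and -0.15 with these covariates. Without vehicle replicate 3 or 4, 3 members fell, Pdk4 with Acadl and Acadm or with Acadm and Hadh, and without vehicle replicate 2, Acsl1 rose (1.08, adjusted p = 0.0171). With the mean of a gene's probe sets 3 fell and 1 rose, and with a common median or the beta-actin covariate 2 fell; these members were named after their values were seen. Pdk4 did not pass without vehicle replicate 1 or BMP7 replicate 2, 3 or 4 (adjusted p up to 0.0859).

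**Figure D3:**
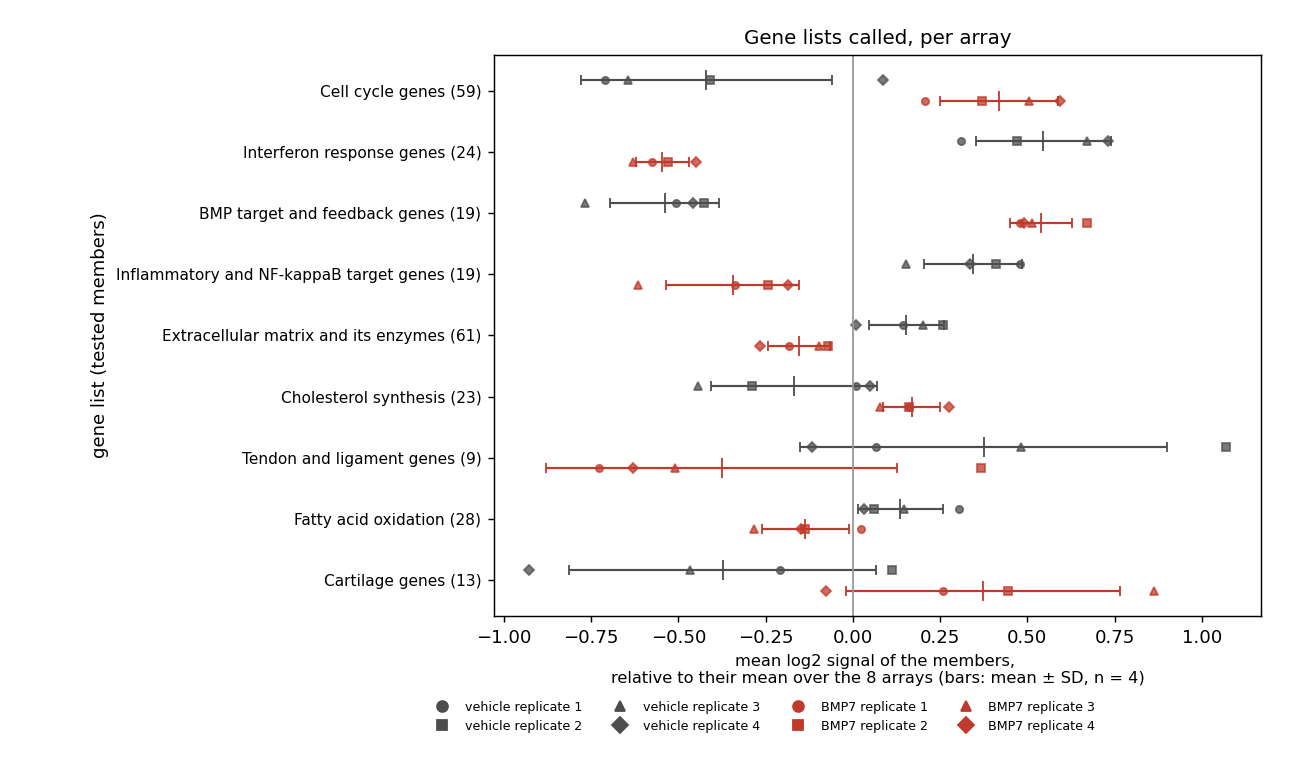
Points give, for each array, the mean log2 signal of a list's tested members relative to their mean over the 8 arrays, with the mean ± SD per group (n = 4; vehicle grey, BMP7 red) and the number of tested members in parentheses. The 4 lists called higher are cell cycle (59 members), BMP target (19), cholesterol synthesis (23) and cartilage genes (13), and the other 5 were called lower.

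Regulators and markers of fat, bone and muscle differentiation were followed whatever their result. The adipogenic regulators Cebpa and Pparg had log2 changes of 0.85 (SE 0.23, adjusted p = 0.0700) and -0.59 (SE 0.24, adjusted p = 0.194) and did not pass. The same held for Dlk1, an inhibitor of adipogenesis (1.13, SE 0.63, adjusted p = 0.323), Ndn (-0.46, adjusted p = 0.436), and Ppargc1a, a coactivator of thermogenic genes (-0.40, adjusted p = 0.549). The bone markers Runx2 and Alpl had -0.61 (SE 0.21, adjusted p = 0.131) and -0.42 (SE 0.32, adjusted p = 0.462); a second, dimmer Runx2 probe set had 0.20. Smooth muscle actin Acta2 had -0.15 (SE 0.19, adjusted p = 0.676), which became 0.24 with quantile normalization, 0.24 with the spike-in covariate and 0.17 with the mean 3'/5' ratio covariate, and Srf had -0.56 (SE 0.23, adjusted p = 0.190) with a second probe set at 0.63. Ucp1, Fabp4, Adipoq, Wnt10a and Myod1 had mean log2 signals over the 8 arrays under the filter level and were not tested. The brightest probe set of Fabp4, a fatty acid binding protein of adipocytes, had mean signals of 253 ± 362 in vehicle and 329 ± 148 in BMP7 (SD, n = 4 arrays each). Its highest signal, 784, was on a vehicle array. Its log2 change was 1.70, and the other Fabp4 probe sets had 0.45, 0.44 and 1.05, all untested and dim. The brown fat uncoupling protein gene Ucp1 had mean signals of 46.2 ± 24.9 in vehicle and 23.0 ± 9.84 in BMP7 (SD, n = 4 arrays each). Of the 39 lists, 37 had at least 5 tested members, 9 were called by camera and 8 by the directional fry test, 5 of them among the 9. The other 3 were skeletal muscle genes, TGF-beta targets and YAP/TEAD targets (fry adjusted p = 0.00546, 0.0397 and 0.0397, each higher).

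The deposited table of the authors held its own comparison. In the authors' deposited table, 2674 of 22690 probe sets had p under 0.05, where chance gives 1134, with 1605 ratios above 1 and 1069 below 1. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 1 probe set remained under 0.05.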

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

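The tests of degraded RNA, of weak labelling and of a wrong label for vehicle replicate 3, those of the gene lists without that array and those with a covariate were chosen after the result was seen. In 190 groups of 4 arrays (named genes, gene lists and array measures), 8 held 1 array far from the other 3, where chance gives about 1 in 20, or 9.5; 4 of these lay in vehicle arrays and 4 in BMP7 arrays.

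The Mcm5 signal was 1845 on vehicle replicate 4 and 801 to 878 on the other vehicle arrays. Tomm40 was at 499.6 on vehicle replicate 2 against 1314 to 1397, and Ddit4 was at 3723 on the same array against 6000 to 6353. Igf2r was at 4375 on BMP7 replicate 3 against 3192 to 3310. On BMP7 replicate 1, Tgfbr2 was at 6279 against 3485 to 3618, Ifit3 at 573 against 511 to 515 and Selenop at 3986 against 1220 to 1311. The beta-actin 3'/5' ratio of vehicle replicate 3 was 6.548, against 1.17 to 1.40 on the other vehicle arrays.

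Vehicle replicate 3 differed from the other 7 arrays in signal and in correlation. BMP7-treated RNA under its label is argued against: on a scale from 0 at the other vehicle arrays to 1 at the BMP7 arrays, 9 BMP target genes called without it had a median position of -0.2553 on it (quartiles -0.477 and -0.118; highest 0.188). Degraded RNA stays undecided: its Gapdh 3'/5' ratio was 2.486 and its beta-actin ratio 4.68 times the highest of the other arrays, but its pyruvate carboxylase ratio of 4.58, with a 5' signal of 374 above the filter level, lay below the 5.49 of vehicle replicates 1 and 2, which goes against degradation in that array alone. The transferrin receptor ratio of 2.26 lay within the range of the others (1.79 to 3.49), from 5' signals under the filter level. By group it ran the other way, at 1.79 to 2.46 on the vehicle arrays and 2.35 to 3.49 on the BMP7 arrays, and it was not part of the mean ratio. Weak labelling or hybridisation stays open too, with a spike-in level 1.506 times the next highest; no biological explanation was tested, since the design gives none within a group.

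Cell cycle genes were higher in BMP7 arrays, with a median log2 change of 0.86 (jackknife SE 0.23). Scaling of the arrays is argued against as the whole cause: after quantile normalization, relative to all genes, the median was 0.8544 (SE 0.229). The same holds for degraded RNA in vehicle replicate 3 alone, since without that array the median was 0.7659 (SE 0.249). Labelling yield and RNA degradation across the arrays cannot be told apart from BMP7, because the spike-in level and the 3'/5' ratios overlap with group: with the spike-in level as a covariate the median was 0.5956 (SE 0.501), with the mean 3'/5' ratio it was 0.6287 (SE 0.447), and no member passed in either (0 of 59), the wider error being part of the reason. A response of the cells to BMP7 stays open, as a hypothesis.

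Interferon response genes were lower in BMP7 arrays, with a median of -0.86 (jackknife SE 0.0835). The median was -0.9455 (SE 0.0536) after quantile normalization relative to all genes and -0.886 (SE 0.101) without vehicle replicate 3. Both lay below 0 by more than 2 SE, which argues against scaling and degraded RNA in that array alone as the whole cause. With the spike-in level as a covariate the median was -0.931 (SE 0.285), and with the mean 3'/5' ratio it was -0.922 (SE 0.237), again beyond 2 SE. These values argue against labelling yield and degradation across the arrays only as far as the covariates measure them. Both covariates overlap with group, and 3 members fell with the first and 5 with the second, in place of 6. A lower interferon response after BMP7 is a candidate explanation, found and tested on the same arrays. A difference between the cultures unrelated to BMP7 stays open, since the labels name no culture or day.

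Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many changed probe sets (404, highest other 0). The same held for probe sets changed at least 2-fold (334, highest other 0) and for genes (265, highest other 0). These counts go against chance at a share of 0.05 only if all 8 arrays can be exchanged freely, and 35 splits can give no share under 0.0286. The splits took no account of the replicate numbers, though 7 of 8 arrays correlated best with their own number. Chance is therefore not excluded by these counts. The real split also called the most lists (9), but 4 others called 7 each while 0 genes changed in them. The list count therefore cannot exclude chance, since lists were called at the preset correlation where no gene passed.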

How the results depend on the processing

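The fits with a spike-in, beta-actin or mean 3'/5' ratio covariate and the unequal-variance test on linear signals were chosen after the result was seen. Of the 404 probe sets, 100% of those tested in each alternative kept their direction, and 68 named genes kept their sign in every fit that tested them. Both sets had been picked from the arrays that these fits reuse, so kept directions are no independent support. Of the 68, 0 passed in all fits, since the test on linear signals ended all of these calls. Of named gene values, 839 outside the leave-one-out fits stayed on their side of the threshold, 242 no longer passed, 12 newly passed and 4 reversed: Acta2 was at 0.2419 with quantile normalization, 0.2355 with the spike-in and 0.1713 with the mean ratio covariate, and Srf was at 0.03855 with the mean of its probe sets. The cause was not tested for these or the other changes, unless named. The main counts were 404 probe sets (207 higher, 197 lower), 334 changed at least 2-fold, 265 genes and 9 lists. Array weights gave 1760 (1002 and 758), 748 and 1095; the unmoderated test 83 (39 and 44), 59 and 69; the spike-in covariate 49 (24 and 25), 49 and 38; the mean ratio covariate 92 (42 and 50), 91 and 70; the test on linear signals 4 (2 and 2), 2 and 2. With fewer arrays, leaving out 1 gave 90 to 1042 probe sets (37 to 669 higher, 53 to 373 lower), 90 to 788, 70 to 565 genes and 6 to 9 lists; the lowest came without BMP7 replicate 2 or 3, for lists without vehicle replicate 3, and the highest count of probe sets without vehicle replicate 4. Lists called numbered 1 with an estimated correlation, 32 with mixed fry, 5 with the beta-actin covariate and 6 with the mean ratio covariate. Lists called under a camera alternative and not as reported were skeletal muscle (common median, no intensity trend, without BMP7 replicate 1), unfolded protein response (quantile normalization, mean of probe sets, without BMP7 replicate 3) and oxidative phosphorylation genes (spike-in covariate).

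List p-values over the leave-one-out fits ran from 2.258e-24 to 6.512e-17 for cell cycle, 8.24e-14 to 9.121e-09 for interferon, 2.062e-08 to 1.676e-06 for BMP targets, 7.583e-06 to 0.001786 for inflammatory, 8.851e-05 to 0.00274 for matrix, 0.003537 to 0.0483 for cholesterol, 0.001223 to 0.09734 for tendon, 0.01353 to 0.1138 for fatty acid oxidation and 0.0143 to 0.4005 for cartilage genes. Calls ended, by adjusted p, for matrix with quantile normalization (0.1832); cartilage with no filter (0.07078), the stricter filter (0.1348), array weights (0.07756), the mean of probe sets (0.08595), fry (0.1136) and the beta-actin covariate (0.06575); and inflammatory genes with the stricter filter (0.325), which tested fewer members. Cholesterol synthesis lost its call with array weights (0.07756), fry (0.1136), mixed fry (0.1574) and the spike-in (0.5768), beta-actin (0.06269) and mean ratio (0.1891) covariates, tendon with array weights (0.09652), fry (0.08525), and these covariates (0.1278, 0.06575 and 0.126), and fatty acid oxidation with fry (0.09032) and these covariates (0.1275, 0.06575 and 0.1391). With an estimated correlation the values were 0.2905 for cell cycle and matrix, 0.05039 for BMP target and inflammatory, 0.5609 for cholesterol and fatty acid oxidation, 0.3281 for tendon and 0.5904 for cartilage genes.

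With the replicate number as a block, 591 probe sets passed, 327 higher and 264 lower, and 380 genes, and the 9 lists stayed called. Of 68 named genes, 66 passed with the block, and Igf2r (adjusted p = 0.0634) and Irs1 (0.0556) did not. With it 21 cell cycle genes rose in place of 11, and 9 BMP target genes in place of 8, as Id1 passed (0.0391). Further, 2 cartilage genes fell in place of 0, 2 fatty acid oxidation genes fell in place of 1, and 1 inflammatory gene rose in place of 0. Interferon and inflammatory genes that fell numbered 7 each in place of 6. Same-numbered arrays deviated from their group means with r = 0.37, 0.036, 0.15 and 0.18, so 3 of 4 pairs were over 0.1 and the numbers were not taken as pairs; 7 of 8 arrays correlated best with their own number, a hint from the data. List tests were not run for the unmoderated test and the test on linear signals. The second value table gave no separate fit, since its group means equalled those of the values used and its per-sample columns matched no label. Without detection calls, signal over background is unknown, and folds from means under the filter level of 323 are the least certain.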

Other observations

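The fits with the spike-in level as a covariate were chosen after the result was seen, as was the test of the glucocorticoid list, of which at least 3 members (Mt1, Ddit4 and Nfkbia) had been seen; the genes that prompted it and the complement list were left out. The 28 other lists tested were not called by camera, yet single members passed in limma. TGF-beta target genes went both ways: of 23 tested, 3 rose, among them Ccn2 and Smad7, Tgfbi fell (log2 change -1.41, SE 0.31) and 19 did not pass (5 rose and 5 fell adjusted over the list alone; median 0.04, adjusted p = 0.893, by fry 0.0397). Ccn2 was also the 1 of 18 YAP/TEAD targets that rose (6 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.280, by fry 0.0397). Receptors moved in opposite directions: Fgfr3 rose, while Fgfr1, Pdgfra and the feedback inhibitor Spry2 fell (-1.03, -1.28 and -1.13) among 25 FGF, PDGF and VEGF genes (2 and 5 adjusted over the list alone; median -0.16, adjusted p = 0.433), with a second Fgfr1 probe set at 0.66 and a second Pdgfra probe set at -0.15. Tgfbr2, the type II TGF-beta receptor, fell by 1.44 among 19 BMP and activin receptors, Smads and ligands (0 and 1; median 0.17, adjusted p = 0.806), with a dimmer probe set at 0.13. The metallothioneins Mt2 and Mt1 fell by 2.01 and 1.52 while Nqo1 and Prdx6, antioxidant enzymes, rose by 1.41 and 1.33 among 28 antioxidant genes (3 and 5; median -0.05, adjusted p = 0.442). Of 20 IGF and insulin genes, Socs3, a feedback inhibitor of cytokine signalling, fell by 1.67, Igf2r fell by 0.75 and Irs1 rose by 0.82 (2 and 3; median 0.22, mean -0.01, adjusted p = 0.959), with a second Igf2r probe set at -0.30. With the mean of their probe sets, Fgfr1, Pdgfra, Tgfbr2 and Igf2r had -0.19, -0.72, -0.66 and -0.53 and did not pass (adjusted p = 0.658, 0.0834, 0.411 and 0.154). Other Tgfbi probe sets had -1.30, -0.90 and -1.53 and did not pass (limma adjusted p = 0.0566, 0.152 and 0.0565). Mt2, Socs3, Smad7, Ccn2 and Fgfr3 passed in every leave-one-out fit that tested them. Fgfr1 and Tgfbr2 did not pass without BMP7 replicate 2, 3 or 4 (adjusted p up to 0.0574 and 0.0632), Pdgfra, Mt1 and Prdx6 without these or vehicle replicate 1 (up to 0.0817, 0.0817 and 0.106), Nqo1 and Irs1 without vehicle replicate 1 or any 1 BMP7 replicate (up to 0.0917 and 0.167), Tgfbi without vehicle replicate 1 or BMP7 replicate 1, 2 or 3 (up to 0.132), Spry2 without vehicle replicate 1 or 2 or any 1 BMP7 replicate (up to 0.148), and Igf2r passed in 0 of the 8 fits (0.0581 to 0.158).

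Lineage and pathway lists held few calls. Single members that passed were Ebf1, an adipogenic transcription factor (-1.48, of 17; median -0.04, adjusted p = 0.806), Angptl4 (of 19 adipocyte genes; median 0.29, adjusted p = 0.433), Sox9 (of 28 inhibitors of adipogenesis; median 0.13, adjusted p = 0.728), Gas1 (-1.04, of 10 Hedgehog genes; median 0.46, adjusted p = 0.806), Meis1 (-1.20, of 19 homeobox genes; median -0.11, adjusted p = 0.806), Cyp1b1 (-1.62, of 10 retinoid and steroid genes; median 0.04, mean -0.15, adjusted p = 0.806), Ddit4 (-0.97, of 26 hypoxia and glycolysis genes; median -0.04, adjusted p = 0.846), Tomm40 (1.34, of 26 mitochondrial biogenesis genes; median 0.09, adjusted p = 0.728) and Stmn2 (1.40, of 7 neuronal and glial markers; median -0.10, mean 0.07, adjusted p = 0.959). Hey1 and Lfng (1.25) rose among 15 Notch genes (median -0.13, mean 0.19, adjusted p = 0.806), Ly6a rose by 0.89 while Vcam1 and Pdgfra fell among 15 mesenchymal progenitor markers (median 0.07, mean -0.00418, adjusted p = 0.946), and Actn4 rose by 1.24 while Fhl2 fell by 1.03 among 30 smooth muscle genes (median 0.06, mean 0.04, adjusted p = 0.959). A second Cyp1b1 probe set had -0.80, and Cyp1b1 did not pass with the mean of its probe sets (-1.21, adjusted p = 0.117). Other Ebf1 probe sets had -0.75 and -0.98 and did not pass (limma adjusted p = 0.263 and 0.0722). Stmn2 was at 2.15 without vehicle replicate 2. Of the genes named so far in this part, Ccn2, Fgfr3, Socs3, Hey1, Vcam1 and Fhl2 passed with the spike-in level as a covariate. Gas1 did not pass without BMP7 replicate 3 (0.0506), Actn4 without BMP7 replicate 2 or 3 (up to 0.0516), and Tomm40, Stmn2, Lfng and Fhl2 without vehicle replicate 1 or any 1 BMP7 replicate (up to 0.143, 0.151, 0.0809 and 0.136). Meis1 and Ly6a did not pass without these or vehicle replicate 2 (up to 0.112 and 0.129), Ddit4 without these or vehicle replicate 4 (up to 0.158), and Ebf1 and Cyp1b1 without vehicle replicate 1 or 2 or BMP7 replicate 2, 3 or 4 (up to 0.0982 and 0.110). The median, mean and test differed in sign for the retinoid, mesenchymal, smooth muscle, neuronal and osteoblast lists, where the test direction was lower, and for the Notch and IGF lists, where it was higher. Adjusted over each list alone, the counts that rose and fell were 1 and 1 for adipogenic factors, 4 and 1 adipocyte, 3 and 1 inhibitors of adipogenesis, 2 and 1 Hedgehog, 2 and 2 homeobox, 1 and 2 retinoid, 2 and 2 hypoxia, 1 and 0 mitochondrial, 1 and 0 neuronal, 3 and 1 Notch, 3 and 4 mesenchymal, and 4 and 4 smooth muscle. No member passed (0) in limma among 17 osteoblast genes (2 and 5 adjusted over the list alone; median -0.02, mean 0.02, adjusted p = 0.808), 6 skeletal muscle genes (3 and 0; 0.57, adjusted p = 0.0558, by fry 0.00546, with a common median 0.0374, without the intensity trend 0.0459 and without BMP7 replicate 1 0.0487), 11 brown and beige fat genes (0 and 0; -0.13, adjusted p = 0.806), 20 Wnt genes (0 and 0; 0.12, adjusted p = 0.806), 21 p53 targets and CDK inhibitors (2 and 4; -0.04, adjusted p = 0.946), 28 unfolded protein response genes (0 and 0; 0.17, adjusted p = 0.103, with quantile normalization 0.0306, with the mean of probe sets 0.0374 and without BMP7 replicate 3 0.0473), 61 oxidative phosphorylation genes (0 and 0; -0.05, adjusted p = 0.806, with the spike-in covariate a median of 0.11 and 0.0460), 19 fatty acid synthesis genes (0 and 0; 0.08, adjusted p = 0.478) or 13 reference genes (0 and 0; -0.27, adjusted p = 0.280). Among markers of other cell types, 0 of 6 macrophage and leukocyte markers (0 and 1; -0.16, adjusted p = 0.478), 0 of 4 endothelial (0 and 1; median 0.14) and 0 of 2 epithelial markers (0 and 0; median -0.01) passed, and the last pair of lists was too small for the list test.

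The falls of Mt2, Angptl4 and Pdk4 prompted the hypothesis of a lower glucocorticoid response, and a list of 30 glucocorticoid-induced genes without them and Ampd3, 8 of them also in the lists above, was tested. Its median over 24 tested members was -0.1874, and 4 fell (Mt1, Aqp1, Sult1a1 and Ddit4, the middle pair named after their values were seen), but camera gave p = 0.0787 with the preset correlation and 0.188 with an estimated one, which leaves the hypothesis undecided. Without the 8 members in the lists above, 16 were tested and 2 fell, and limma's camera test gave p = 0.155 with the preset and 0.178 with an estimated correlation. C1s1 prompted a list of 25 complement genes without it, of which 8 were tested: the median was -0.01164, C1ra alone fell (-1.60; named after its values were seen), and limma's camera test gave p = 0.194 with the preset and 0.405 with an estimated correlation. Members went both ways (4 and 4), so a lower complement expression as a group was neither borne out nor excluded.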
